A study of Mus musculus with 2 samples.

How the data were processed

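Gene expression of 2 subsets of dendritic cells from mouse spleen was measured on 1-colour Affymetrix arrays, 1 array per subset. Per the labels' protocols, spleens of C57BL/6J mice aged 6 weeks were digested with collagenase and DNase, mononuclear cells were taken from a Percoll gradient, and the suspension of 30 mice was pooled. Cells bearing CD3, B220, Ter119 or DX5 were removed with magnetic beads, which targets T cells, B cells, erythroid cells and natural killer (NK) cells. CD11c+CD8α+ and CD11c+CD8α− cells were then sorted by flow cytometry, and their total RNA was amplified by an in vitro transcription method that starts at the 3′ end and labelled with biotin. Both arrays therefore come from 1 pool of animals, and neither subset has a replicate.

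The deposited values are signal intensities per probe set on a linear scale. Per the submitters' processing notes they were made with MAS5, the Affymetrix method that summarises the perfect-match and mismatch probes of a probe set on each array by itself. Its version and settings are not given in the sources used here. The authors' scaling was read from the values. After the lowest and highest 2% of values were removed, the mean intensity was 500.0 on each array. Detection calls were not used here. MAS5 estimates the background locally for each probe set, so that intensities in the lower part of the range scatter widely between arrays and a fold change there is unreliable.

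Each array carried 45037 probe sets besides 64 control probe sets, which were left out of the gene comparisons. Through the platform annotation, 34945 probe sets had 1 gene symbol, 932 had several and 9160 had none here; only the first kind was used for genes. The gene IDs of 34741 of them were found in the RefSeq gene table of assembly GRCm38.p6, which changed 0 symbols. The table served only for names and for the order of genes, and no coordinates are printed because no build is named for these values. Among the 18193 genes, the probe set with the highest mean log2 signal over both arrays stood for each gene. List genes without a probe set of their own name were not analysed here.

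Before log2 was taken, signals below the 50th percentile of an array were raised to that percentile, which was 74.9 on the CD8α− array and 68.8 on the CD8α+ array. A gene counted as measured when at least 1 array lay above its floor, which held for 11625 genes. Where 1 array was at the floor, the fold is a lower bound and is written "at least"; a bound under 1-fold was set to no difference. Ratios are CD8α+ over CD8α−. With 1 array per group no test between the subsets was possible, and genes were counted by a rule of size, at least 2-fold. The number of arrays limits the precision of every value.

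Technical disagreement was gauged from genes with at least 2 probe sets above the floor on both arrays. The SD of the difference between the log2 ratios of a gene's brightest and second-brightest probe sets was 0.65, 0.52 and 0.32 in the lowest, middle and highest of 3 equal classes of signal. This includes differences in transcript isoforms and in probe specificity, and it leaves out the variation between animals, sorts and labellings. The procedure was tested on simulated data with 11251 measured genes and 200 altered genes. Noise was set so that 2 probe sets of a gene would disagree by the SDs above. Below the floor it was that of the lowest class. Of the genes simulated at 4-fold, 94.0% were called at least 2-fold; at 8-fold the share was 98.0% and at 2-fold itself 41.7%. Of 11055 genes simulated without a difference, 0.85% were called, a share that leaves out noise between sorts and labellings.

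The 30 gene lists, the floor, the fold limit and the rule for named genes were fixed before the data were examined. A list's median log2 ratio was placed among the medians of 10000 random lists of the same size, drawn from measured genes in 20 bins of mean signal; this describes these 2 arrays and is not a p-value. Named genes were the 12 with the highest and the 12 with the lowest ratio above the floor on both arrays, the 5 largest bounds in each direction, the sort genes with Cd8b1, Itgam, Sirpa and Cd4, and up to 6 members of each list with the largest ratios. For the first 2 of these parts all measured probe sets of a gene had to point the same way, and clone names such as those ending in Rik were left out. All members of the housekeeping and sex-linked lists could be named. Outside this rule, members that completed a small count (Batf3, Il12b, Wdfy4, Id2, Nfil3, Psmb9, Tpp1, Scarb1, Ly75, Cd81, Itga3, Itgb3, F11r, Mx1, Mx2, Trim30a and Treml4) and Csf1r were chosen after their values were seen, as were the genes first named in the closing section. Also named outside this rule were H2-Aa, H2-Ab1, H2-Eb1, Cd74, H2-DMa, H2-K1, H2-D1 and B2m. A further 3 lists were drawn up after the data had been seen.

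Alternatives were centring each array on its median, quantile normalization, loess of the ratio on mean signal (span 0.3), floors at the 30th and 70th percentiles, no floor, the mean over a gene's measured probe sets, only probe sets with a plain _at ending, the probe set with the smallest ratio, and a fold limit of 3. The smallest ratio means the smallest difference between the arrays, in either direction. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9 were used.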

Results

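The study compared the transcripts of CD8α+ and CD8α− dendritic cells (DCs) of the mouse spleen. DCs take up antigen and present it to T cells. The CD8α+ subset, now called cDC1, is known for presenting engulfed antigen on MHC class I, and the CD8α− subset, mostly cDC2, for presenting on MHC class II to CD4 T cells. Cells were pooled from 30 mice, so each subset was measured once, on 1 array, and no difference has a replicate check or a p-value. On the CD8α− array signals ran from 0.36 to 53690.5 with a median of 74.9, and on the CD8α+ array from 0.19 to 52359.7 with a median of 68.8. Across the 9998 genes above the floor on both arrays, the log2 signals correlated with r = 0.92, where genes are not independent replicates.

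Of 11625 measured genes, 726 were at least 2-fold higher in CD8α+ DCs and 902 at least 2-fold lower, while 9997 (86.0%) lay within 2-fold. At 8-fold the counts were 53 higher and 41 lower, and at 16-fold 20 higher and 10 lower. Of the 2-fold calls, 103 of the higher and 191 of the lower were lower bounds because 1 array was at the floor. The higher calls made up 44.6% of the total. The median log2 signal of all probe sets stood at -0.12 on the CD8α+ array relative to the CD8α− array, and ratios are given without removing this shift. The median log2 ratio of the measured genes was -2.0e-04 without centring and 0.11 with it. After each array was centred on its median, there were 932 higher and 714 lower calls and the share of higher calls was 56.6%. Of 508 genes called by their brightest probe set that had a second probe set above the floor, the second pointed the same way in 466 (91.7%) and was itself at least 2-fold in 276 (54.3%). Folds below are those of the brightest probe set. Other probe sets of a gene can fall short of 2-fold even where this is not stated.

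Of the genes used for the sort, Cd8a separated the arrays and Itgax did not. Cd8a, the α chain of CD8, had a signal of 17850.3 in CD8α+ DCs and 102.8 in CD8α− DCs, a 174-fold difference, and its 5 probe sets gave log2 ratios from 3.45 to 7.44. Itgax, which encodes CD11c, was bright in both subsets, at 8957.3 in CD8α+ and 15286.9 in CD8α− DCs, 1.71-fold lower in the former. Surface molecules of the CD8α− subset were lower in CD8α+ DCs. Sirpa, the receptor for CD47, was 15.3-fold lower with log2 ratios from -3.93 to -3.09 over 3 probe sets. Itgam, which encodes CD11b, was 7.34-fold lower, and Cd4 at least 10.8-fold lower. Cd8b1, the β chain of CD8, was 3.91-fold higher in CD8α+ DCs by its single probe set, with signals of 916.3 and 234.1.

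Among genes above the floor on both arrays, those with the highest ratios were, after Cd8a, the chemokine receptor gene Xcr1 (62.5-fold), the lipid phosphatase gene Plpp1 (48.5-fold) and the protein disulfide isomerase gene Pdia5 (47.6-fold). P2ry14, a receptor for UDP-sugars, was 32.7-fold higher and Itgae, the CD103 integrin chain, 31.1-fold. The small GTPase gene Rab7b was 29.2-fold higher, the prolyl hydroxylase gene P3h2 27.1-fold, the lysosomal amidase gene Naaa 24.5-fold and the adhesion molecule gene Cadm1 23.5-fold. Dbn1, which encodes the actin-binding protein drebrin, was 22.3-fold higher and Serpinf1 21.3-fold, although the probe sets of Serpinf1 ranged from 1.07 to 4.41 on the log2 scale. Xcr1, Plpp1, Itgae and P3h2 had signals of 95.3, 98.1, 92.0 and 83.3 in CD8α− DCs, little above the floor of 74.9. The size and order of these folds are therefore uncertain. Among genes at the floor in CD8α− DCs, Hepacam2 was at least 40.1-fold higher, Ttc39a at least 30.4-fold, the Wnt receptor gene Fzd1 at least 24.2-fold, and Gcsam and the prostacyclin synthase gene Ptgis at least 18.7-fold each.

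On the other side, the matrix metalloproteinase gene Mmp12 was 31.0-fold lower in CD8α+ DCs, Sirpb1a 30.6-fold and Ptger3, a prostaglandin E receptor, 26.6-fold. Dtx1, a Notch pathway gene, was 19.6-fold lower, the interferon-inducible gene Rtp4 19.3-fold and Tlr7, a receptor for single-stranded RNA, 19.0-fold. The 2 probe sets of Rtp4 gave log2 ratios of -4.27 and -0.80. The transglutaminase gene Tgm2 was 18.4-fold lower and among the brightest of these, with signals of 19970.1 in CD8α− and 1085.2 in CD8α+ DCs and log2 ratios from -4.34 to -3.41 over 5 probe sets. Adgre1, which encodes the macrophage antigen F4/80, was 16.5-fold lower, Npl 16-fold, the C-type lectin gene Clec4a3 15.4-fold and the complement gene C1qb 13.7-fold. In CD8α+ DCs, Mmp12, Sirpb1a, Ptger3, Tlr7 and C1qb had signals of 103.2, 99.5, 100.8, 101.0 and 82.0. These lay little above the floor of 68.8, so the size and order of their folds are uncertain. Bounds of at least 15.6-fold for C1qa, 10.3-fold for Oas2, 9.04-fold for C1qc and 8.43-fold for Hebp1 came from genes at the floor in CD8α+ DCs.

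**Figure D1:**
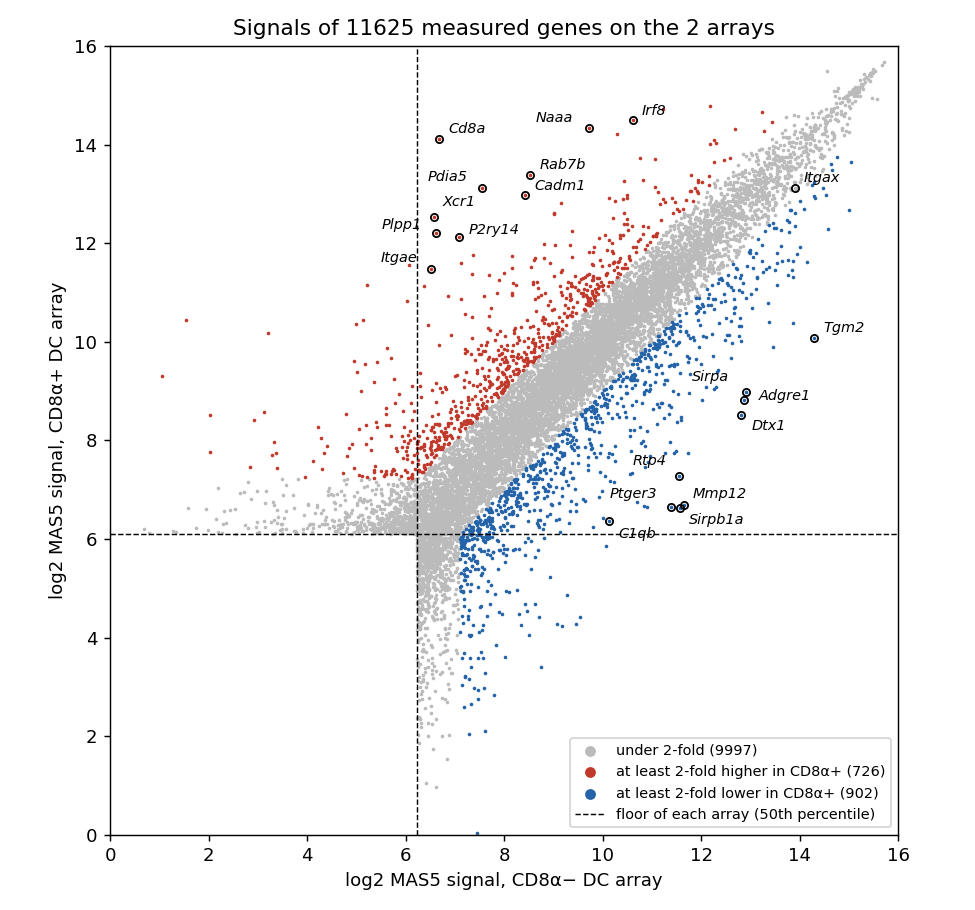
Log2 MAS5 signal of each measured gene on the CD8α− array (x axis) and the CD8α+ array (y axis), 1 point per gene, with dashed lines at the floor of each array. The 726 red genes were at least 2-fold higher and the 902 blue genes at least 2-fold lower in CD8α+ DCs; circled genes are examples named in the text, and Cd8a lies furthest from the diagonal among genes above the floor on both arrays.

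The 2 lists of subset genes moved in opposite directions. Of 26 measured cDC1 genes, 21 were at least 2-fold higher in CD8α+ DCs, 0 were 2-fold lower, and the median log2 ratio was 3.48, above all 10000 random lists matched on signal. Besides Cd8a, Xcr1, Plpp1, Itgae, Rab7b, Naaa, Cadm1, Hepacam2 and Gcsam, the 21 included Irf8, a transcription factor that cDC1 require, which was 14.8-fold higher. The other 5 members were Batf3, Il12b, Wdfy4, Id2 and Nfil3, with log2 ratios of 0.98, 0.77, 0.71, 0.03 and -0.42. Of 26 measured cDC2 genes, 19 were at least 2-fold lower and the median was -2.08, below all 10000 random lists. Besides Dtx1, Tlr7, Sirpa, Cd4 and Itgam, the C-type lectin gene Clec4a2 was 12.9-fold lower. The only cDC2 member at least 2-fold higher in CD8α+ DCs was Ccr2, a chemokine receptor of monocytes, at 5.83-fold, and its 4 probe sets ranged from 0.56 to 2.54 on the log2 scale. The cDC2 list shares Csf3r with the neutrophil marker list and Csf1r and Ccr2 with the monocyte and macrophage list, and both of those lists had medians below 0 as well (-0.77 and -0.89). Both subset lists were drawn up from general knowledge of these cells and not from these arrays.

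Genes common to DCs had a median of -0.01 over 12 members, at the 46.9th percentile of random lists, which was 0.11 after median centring. Of the 12, 10 lay within 2-fold. Mycl, a MYC family factor of DCs, was 3.38-fold higher in CD8α+ DCs, and Ccr7, the receptor for migration to lymph nodes, was 2.0-fold lower.

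Most antigen presentation genes lay within 2-fold, and those that differed went both ways. In the MHC class I and cross-presentation list, 5 of 24 members were at least 2-fold higher in CD8α+ DCs and 2 at least 2-fold lower, with a median of 0.32 at the 99.9th percentile. The 5 were Tapbpl (3.62-fold), Pdia3 (2.61-fold), the peptide transporter genes Tap1 (2.38-fold) and Tap2 (2.09-fold), and the immunoproteasome gene Psmb9 (2.02-fold). The other probe sets of Tapbpl and Tap1 had log2 ratios of 0.31 and 0.32. The 2 lower members were Cybb (3.96-fold) and Rac2 (2.08-fold), which belong to the phagocyte NADPH oxidase rather than to peptide loading. In the MHC class II list, 2 of 18 members were at least 2-fold lower, the lysosomal proteases Lgmn (3.19-fold) and Ctsd (2.55-fold), and the median was -0.45 at the 0.09th percentile. H2-DMb2, a chain of the peptide-loading molecule, was 1.92-fold lower and H2-Oa 1.73-fold. By their brightest probe sets, the class II chain genes H2-Aa, H2-Ab1 and H2-Eb1 had log2 ratios of 0.07, 0.04 and -0.002. Cd74 and H2-DMa had -0.06 and -0.04. The class I genes H2-K1, H2-D1 and B2m had -0.12, 0.01 and -0.23. The lowest of their probe sets reached -0.51 for H2-Aa, -0.47 for H2-DMa, -0.44 for H2-K1 and -0.53 for H2-D1. Those of H2-Ab1 stayed between -0.03 and 0.04. H2-Aa had signals of 45574.9 in CD8α− and 47723.6 in CD8α+ DCs, near the highest signals of each array. Whether ratios hold at such signals was not tested. Marchf1, a ubiquitin ligase that removes MHC class II from the surface, was 2.89-fold higher. The lysosome and phagosome list had a median of -0.41 at the 0.09th percentile, with 5 of 25 members at least 2-fold lower, Cybb, Ctsa (3.56-fold), Npc1 (2.83-fold), Gla (2.79-fold) and Tpp1 (2.13-fold). Within it Ppt1 and Gusb, both lysosomal hydrolases, were 11.4-fold and 7.85-fold higher; Gusb is also on the housekeeping list, and both of its probe sets were at least 2-fold higher. The marker lists of T cells, B cells, neutrophils, and monocytes and macrophages were lower in CD8α+ DCs too, with medians of -0.73, -0.69, -0.77 and -0.89.

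Receptors for microbial products were unevenly spread. Of 27 Toll-like and cytosolic receptor genes, 2 were at least 2-fold higher in CD8α+ DCs, namely Tlr3 (at least 10.9-fold), a receptor for double-stranded RNA, and Tlr12 (at least 10.4-fold). A further 8 were at least 2-fold lower. They included Tlr7, Tlr1 (7.82-fold), the cytosolic RNA sensor gene Ddx58 (6.30-fold) and the flagellin receptor gene Tlr5 (2.60-fold). The other probe set of Ddx58 had a log2 ratio of -0.43. The list median of -0.20 lay at the 4.18th percentile. C-type lectin and scavenger receptors shifted further, with a median of -1.73 below all 10000 random lists. Over the processing alternatives this median ran from -1.82 to -0.87. Here 11 of 18 members were at least 2-fold lower, among them Clec4a3, Clec4a2, Clec4n (9.46-fold) and Cd300lf (6.92-fold), and 5 were at least 2-fold higher. The 5 were Cd207 (14.9-fold), the lectin langerin, the scavenger receptor genes Cd36 (12-fold) and Scarb1 (2.33-fold), Ly75 (4.50-fold), which encodes the endocytic receptor DEC-205, and Cd209d (3.20-fold). Beside these receptors, the monocyte and macrophage marker list had a median of -0.89.

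Among 28 measured cytokine and chemokine genes, 6 were at least 2-fold higher and 8 at least 2-fold lower, and the median of -0.15 lay at the 9.90th percentile and was 0.05 with probe sets of a plain _at ending. Cxcl9 and Cxcl10, the ligands of Cxcr3, were 15.4-fold and 4.31-fold higher in CD8α+ DCs. Vegfa was 7.09-fold lower, Ccl9 5.47-fold, the lymphotoxin gene Ltb 5.17-fold and Osm 3.81-fold. Of 34 receptor genes, 3 were at least 2-fold higher, namely Xcr1, Cxcr3 (10.3-fold) and Ccr2. A further 8 were at least 2-fold lower, among them Ackr3 (7.42-fold), Il21r (5.29-fold) and the decoy receptor gene Il1r2 (4.98-fold), with a list median of -0.24 at the 0.81st percentile. Csf3r and Csf1r, also on the neutrophil and the monocyte and macrophage lists, were 4.13-fold and 4.31-fold lower. In the costimulation and checkpoint list, 1 of 28 members was at least 2-fold higher, the inhibitory receptor gene Btla (5.66-fold), and 5 were at least 2-fold lower. Besides Sirpa these were Tnfsf14 (11.8-fold), Nectin2 (2.56-fold) and the PD-1 ligand genes Pdcd1lg2 (4.94-fold) and Cd274 (2.45-fold). The other probe set of Nectin2 had a log2 ratio of -0.32. The list median was -0.14 at the 11.3rd percentile.

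Of 50 transcription factor genes of the DC lineage, 2 were at least 2-fold higher in CD8α+ DCs, Irf8 and Mycl, and 10 were at least 2-fold lower. The lower ones included Irf4, a factor of cDC2 (5.41-fold), Tbx21 (5.44-fold), Zeb2 (4.43-fold) and Epas1 (at least 2.94-fold), and the median was -0.19 at the 0.67th percentile. In the list of 33 integrins and adhesion molecules the calls were balanced at 5 each way. Itgae, Cadm1, Itga8 (at least 8.49-fold), Cd81 (3.58-fold) and Itga3 (2.82-fold) were higher, and Itgam, Esam (5.56-fold), Cadm3 (4.58-fold), Itgb3 (4.25-fold) and F11r (3.38-fold) lower. The other probe sets of Itga8 and Itga3 had log2 ratios of 0.35 and 0.30. The list median was 0.00 and lay between -0.15 and 0.12 over the processing alternatives.

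Interferon-stimulated genes were split as well. Of 35 measured, 13 were at least 2-fold lower in CD8α+ DCs and 3 at least 2-fold higher, with a median of -0.33 at the 0.30th percentile. Lower members were Rtp4, the antiviral oligoadenylate synthetase genes Oas1a (6.24-fold), Oas2 (at least 10.3-fold), Oas3 (at least 3.97-fold) and Oasl2 (6.02-fold), and Ifit3 (4.63-fold). The 3 higher members were the antiviral GTPase genes Mx1 (3.50-fold) and Mx2 (at least 3.08-fold) and Trim30a (2.18-fold). Beside this list, 13 T cell markers had a median of -0.73 and 14 neutrophil markers -0.77. Immediate early and stress genes had a median of -0.40, at the 0.03rd percentile, but only 2 of 27 reached 2-fold, Gadd45g (2.39-fold lower) and Gadd45b (2.07-fold lower). Over the processing alternatives their median ran from -0.40 to -0.15, and that of the interferon-stimulated genes from -0.34 to -0.17. The 3 probe sets of Gadd45b ran from -1.26 to 0.14, so that its direction depends on the probe set. Egr1, Egr2, Fosb and Nr4a1 were 1.87, 1.77, 1.66 and 1.57-fold lower.

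Genes of the cell cycle and of oxidative phosphorylation differed less than those of glycolysis. None of 38 cell cycle genes and none of 32 oxidative phosphorylation genes reached 2-fold. The cell cycle median was -0.09 at the 11.8th percentile and 0.03 after median centring, and its largest ratio was that of Cdc45, a replication factor, 1.97-fold higher. The oxidative phosphorylation median was 0.15 at the 98.3rd percentile. Cycs, the cytochrome c gene, was 1.55-fold higher by its brightest probe set and had a log2 ratio of -0.17 by its lowest. In the glycolysis list, 3 of 18 genes were at least 2-fold higher, Hk3 (12.1-fold), Aldoc (4.96-fold) and Pfkp (2.28-fold). The other probe set of Aldoc had a log2 ratio of 0.38. Another 3 were at least 2-fold lower, namely the glucose transporter genes Slc2a3 (5.23-fold) and Slc2a1 (2.59-fold) and the hexokinase gene Hk1 (2.04-fold). The glycolysis median of 0.51 lay at the 99.9th percentile, but it was -0.35 when only probe sets with a plain _at ending were used. Of 20 cholesterol genes, Fdps (3.01-fold) and Lss (2.53-fold), 2 enzymes of the synthesis, were at least 2-fold higher, and the median of 0.25 lay at the 91.7th percentile.

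**Figure D2:**
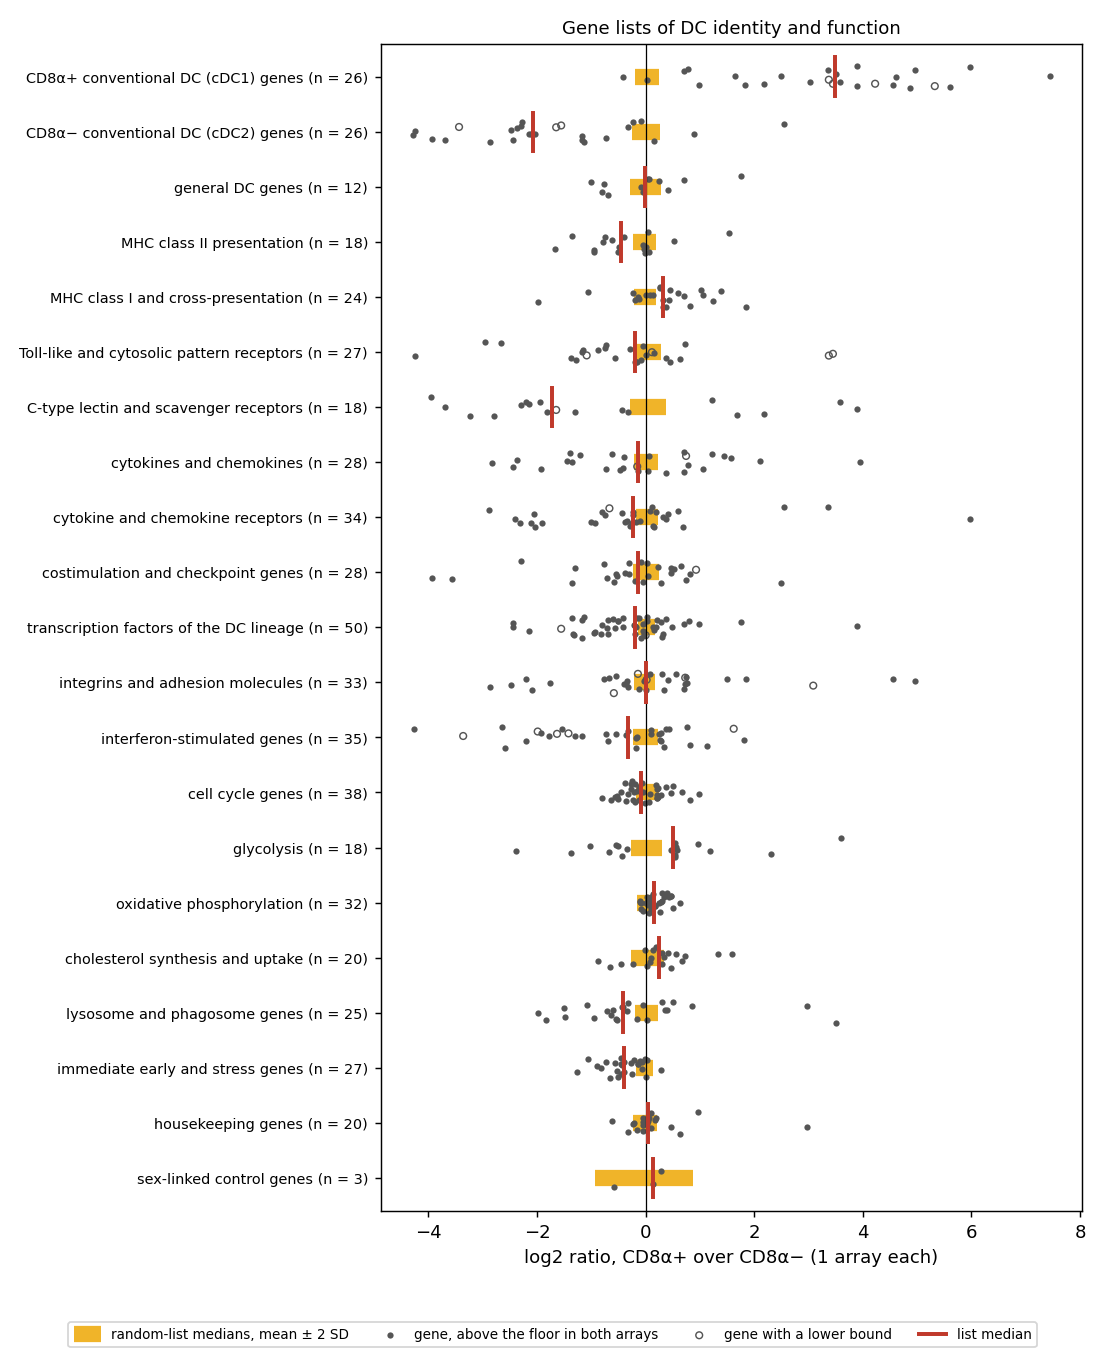
Log2 ratio of CD8α+ over CD8α− signal (x axis) for the measured genes of each list fixed in advance; points are genes, open points have a lower bound, red bars are list medians, and yellow bars span the mean ± 2 SD of the medians of 10000 random lists. The cDC1 list lies furthest right, with a median of 3.48, and the cDC2 list furthest left, with -2.08.

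Control genes mostly had similar signals on both arrays. Of 20 measured housekeeping genes 19 lay within 2-fold, the exception being Gusb, and the median was 0.04, between -0.04 and 0.16 over the processing alternatives. Pgk1 was 1.94-fold higher. Actb was 1.54-fold lower by its brightest probe set and had a log2 ratio of -0.09 by the other, and the 3 actin control probe sets of the array lay between -0.10 and 0.04. The Y-linked genes Kdm5d, Uty and Eif2s3y, read from the same pool of animals on both arrays, had log2 ratios of 0.28, 0.14 and -0.58. Xist was below the floor on both arrays, and Ddx3y was not analysed here. The ratio of 3′ to 5′ signal, a measure of RNA integrity, was 0.77 and 0.78 for Gapdh and 1.16 and 1.10 for β-actin in CD8α− and CD8α+ DCs.

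Markers of other cell types were mostly lower in the CD8α+ sample. The median log2 ratio was -0.73 for 13 T cell markers, -0.69 for 13 B cell markers and -0.77 for 14 neutrophil markers. The first 2 lay at the 0.05th and 0.10th percentiles of random lists and the neutrophil median lay below all 10000. It was -0.64 for 11 erythroid markers and -0.68 for 9 platelet markers, at the 0.93rd and 0.74th percentiles. The platelet median ran from -0.72 to -0.17 over the processing alternatives. In these lists 3, 2, 2, 2 and 2 members, in that order, were at least 2-fold lower. In each of the T cell, B cell and platelet lists 1 member was at least 2-fold higher. Some neutrophil genes were bright in both samples, with S100a8 at 18079 in CD8α− and 9421 in CD8α+ DCs. Lcn2 was 1.97-fold lower and Ltf 1.79-fold, and Csf3r (4.13-fold) and Mmp9 (3.64-fold) were the 2 members past 2-fold. Among T cell genes Zap70, a T cell receptor kinase, was 11.9-fold lower by its brightest probe set, while its 3 probe sets ran from -3.58 to -0.73, and Cd247 was 3.33-fold and Cd5 2.46-fold lower. Cd22, an inhibitory receptor of B cells, was 7.65-fold lower with 2 probe sets at -2.94, Blk was 2.25-fold lower and Fcrla 2.02-fold higher. Of erythroid genes Klf1 (at least 2.69-fold) and Car2 (2.11-fold) were lower. Tspan33, at 2619.9 in CD8α− and 5222.0 in CD8α+ DCs, was 1.99-fold higher. Klf1, Kel, Car1 and Rhag were dim, with signals of 185.3, 132.7, 164.8 and 112.6 in CD8α− DCs. The erythroid genes Hba-a1 and Epb42 and the platelet genes Gp9, Gp1bb, F5 and Tubb1 lay below the floor on both arrays. Of platelet genes Clec1b (3.07-fold) and Ppbp (2.48-fold) were lower and Vwf was 4.0-fold higher. Of the 22 monocyte and macrophage markers, 11 were at least 2-fold lower and 2, Ccr2 and Treml4 (3.79-fold), at least 2-fold higher, with a median of -0.89 below all 10000 random lists. Adgre1, C1qa, C1qb, C1qc and Adgre4 (11.3-fold) were the lowest. NK cell markers went both ways, with a median of -0.14 at the 32.4th percentile that turned to 0.63 with the floor at the 70th percentile, Klrk1 3.48-fold and Gzmb 2.93-fold higher, and Klrd1 3.25-fold, Ccl5 2.61-fold and Klra8 2.03-fold lower. Plasmacytoid DC markers had a median of -0.40 at the 1.51st percentile, which ran from -0.44 to -0.09 over the processing alternatives. Of these markers Klk1 was 3.43-fold and Spib 2.54-fold lower and Cd209d 3.20-fold higher. Stromal and endothelial markers had a median of -0.58 at the 4.37th percentile over 9 genes, which turned to 0.24 with the floor at the 70th percentile. Stab2 was 2.10-fold and Col3a1 at least 2.07-fold lower and Flt1 3.25-fold higher.

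**Figure D3:**
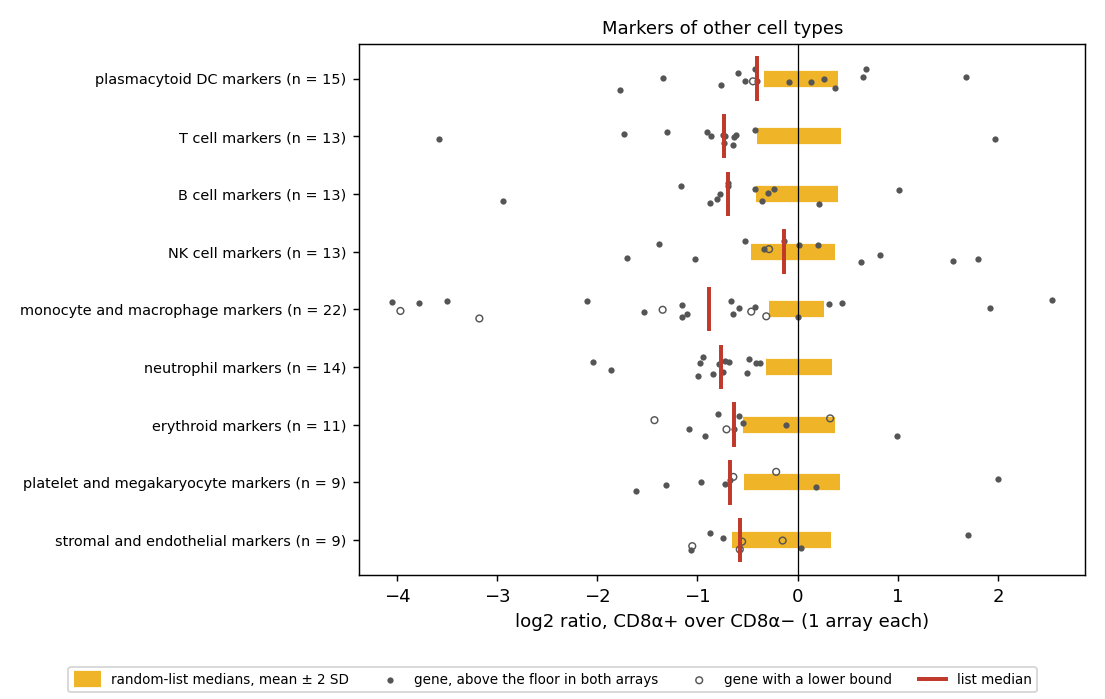
Log2 ratio of CD8α+ over CD8α− signal (x axis) for markers of other cell types, drawn as in the plot of DC gene lists: points are genes, open points have a lower bound, red bars are medians, and yellow bars span the mean ± 2 SD of random-list medians. With the processing drawn here, the medians of the T cell, B cell, neutrophil, erythroid and platelet lists lie close together, between -0.77 and -0.64, while NK cell markers spread to both sides of 0. Over the processing alternatives the platelet median ran from -0.72 to -0.17.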

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

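Apart from the effect of loess on the C1q genes, Adgre1 and Csf1r, the tests of explanations given here were chosen after the results had been seen.

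The 3 control probe sets for 18S ribosomal RNA, which enter no gene comparison, had log2 ratios of 0.94, 0.94 and 0.49 in favour of the CD8α+ sample, above the range of -0.43 to 0.27 over 42 probe sets of spiked-in control transcripts.

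The list medians of neutrophil, T cell, B cell, erythroid and platelet markers were lower in CD8α+ DCs, by similar amounts with the processing used here. Several erythroid and platelet markers lay near or below the floor on the CD8α+ array, which limits their ratios. Over the processing alternatives the platelet median ran from -0.72 to -0.17 and the B cell median from -0.70 to -0.43. The T cell, neutrophil and erythroid medians came no nearer to 0 than -0.61, -0.64 and -0.48. Loess, which takes out the average ratio of genes of like signal, left the list nearest to 0 at a median of -0.59. Loess had little to remove, as 0 of 28 lists besides the cDC1 and cDC2 lists moved beyond 1 SD of their random lists. It also adds little to the comparison with random lists, which were matched on signal. These values therefore argue only against a bias shared by genes of like signal, and other forms of bias were not tested. A larger share of neutrophils in the CD8α− sort is a candidate explanation for the neutrophil markers. The bead depletion did not target these cells, but the CD11c gate should leave them out. S100a8 stood at 18079 and S100a9 at 16356 in CD8α− DCs. The 14 markers had a robust SD of 0.32. The technical SD of a probe set's ratio, 0.46, is that of the lowest class of signal. S100a8, S100a9, Lcn2, Ltf and Chil3 lay in the highest class, where probe sets disagreed less. The spread of the markers therefore cannot decide the question. So narrow a spread is not particular to cells mixed in, as the housekeeping list had 0.21. More of every other cell type in the CD8α− sort stays open, although the beads targeted T cells, B cells, erythroid cells and NK cells. It stays open because the NK cell median lay 0.56 above the median of the 5 lists while the NK cell markers had an SD of 1.04. Expression of these genes by the DCs themselves was not tested.

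Cd8b1, usually read as a marker of CD8 T cells, was higher in CD8α+ DCs by 1.97 on the log2 scale. CD8 T cells in the CD8α+ sort, which the CD3 depletion should remove, would bring other T cell transcripts with them. The other 12 measured T cell markers had a median of -0.74 and 12 of 12 lay below 0. This ratio cannot exclude CD8 T cells, because T cells without CD8 would enter the CD8α− sort and lower it. Hybridization of Cd8a transcripts stays open too, since only 1 probe set stood for Cd8b1 and probe sequences were not used here. Transcription of Cd8b1 in CD8α+ DCs was not tested.

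C1qa, C1qb, C1qc, Adgre1 and Csf1r were lower in CD8α+ DCs with a median of -3.78. Loess left the median at -3.81, which argues only against a bias shared by genes of like signal. It had little to remove, as 0 of 228 named genes moved beyond their technical SD. Of the red pulp macrophage genes checked, Vcam1, Hmox1 and Spic lay above the floor on both arrays, with log2 ratios of 6.1e-05, 0.31 and -1.11. Slc40a1 and Cd5l, at the floor on 1 array, were left out, while C1qa and C1qc were kept as bounds. The median of the 3 genes lay above -3.78 by more than 2 of their SDs (0.75). This cannot decide the question, because the filter drops genes that macrophages in only the CD8α− sort would leave at the floor. DCs may also express the 3 genes themselves. Macrophages that passed the CD11c gate and CD8α− DCs therefore cannot be told apart as sources.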

How the results depend on the processing

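With 1 array per group nothing could be left out, and the choice of processing is all that could be varied. No paired analysis was possible because each subset has 1 sample. Medians count as moved beyond 1 SD of their random lists. The floor and the fold limit set the counts most. With the floor at the 30th percentile there were 1034 higher and 1709 lower genes, at the 70th percentile 483 and 497, and with no floor 2267 and 3219, where genes in the noise of MAS5 enter. A fold limit of 3 left 289 and 326. The other planned settings kept both counts within 1.5 times, and so did 2 settings added after the data were seen: only genes above the floor on both arrays (623 and 711) and 1 common floor (726 and 850). The cDC1 median was 3.60 after median centring, 3.74 with the floor at the 30th percentile or none, 2.76 with it at the 70th, 3.02 with the mean over probe sets, 3.36 with plain _at probe sets and 2.80 with the smallest ratio. The cDC2 median was -1.53 with the floor at the 70th percentile, -1.76 with the mean over probe sets and -1.60 with the smallest ratio. Neither list changed direction under any planned setting. The glycolysis median reversed to -0.35 with plain _at probe sets, and the cause was not tested there, and with the smallest ratio Gadd45b reversed to 0.14 and Cfp to 0.25. The probe sets of these genes disagree, and the cause was not tested. No other named gene past 2-fold, and no other list outside the central 95% of random lists, changed sign. Signals near the floor limit the folds of dim genes.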

Other observations

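The neighbour test was chosen before its result was seen, and the 3 gene lists of the next paragraph were chosen after the named genes had been seen, so their medians are not independent evidence.

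Genes of lipid mediators went different ways. Of 16 measured prostanoid and leukotriene genes, 3 were at least 2-fold higher in CD8α+ DCs and 7 at least 2-fold lower. Ptger3 was 26.6-fold lower, the inducible cyclooxygenase gene Ptgs2 11.2-fold, with signals of 14935 in CD8α− and 1329 in CD8α+ DCs, and Pla2g7 9.75-fold. Those higher were Ptgis (at least 18.7-fold), Tbxas1 (3.23-fold), the thromboxane synthase gene, and Ptger2 (at least 3.23-fold), and the list median was -0.21. Of 12 measured complement genes 5 were at least 2-fold lower and 0 higher, with a median of -0.95. Besides C1qa, C1qb and C1qc they were Cfb (at least 3.33-fold) and the properdin gene Cfp (2.63-fold), whose 2 probe sets pointed in opposite directions. Of 11 purinergic and adenosine receptor genes 3 were at least 2-fold higher and 1 lower, with a median of 0.00. P2ry14 (32.7-fold), P2ry6 (4.02-fold) and P2rx7 (2.69-fold) were higher and P2ry13 (2.86-fold) lower.

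Genes called in the same direction lay next to each other more often than in any of 1000 shuffles. In the order of genes on assembly GRCm38.p6, a run of 7 measured genes from Rasal1 over Dtx1 and the Oas genes to Oas1a was lower in CD8α+ DCs, and a run of 6 from Ppef2 over Naaa to Cxcl9, Cxcl10 and Cxcl11 was higher. Among 11600 genes placed in genome order, 219 neighbouring pairs were both at least 2-fold higher or both at least 2-fold lower, against a mean of 115 and a highest value of 151 when the ratios were shuffled among genes. Without pairs whose names share their first 3 letters, which removes most gene families, 172 such pairs remained against a shuffled mean of 111 and a highest shuffled value of 142. Over all neighbouring pairs, those of opposite direction numbered 81, against a shuffled mean of 112. Without pairs whose names share their first 3 letters they numbered 71, against a shuffled mean of 107. Regulation shared between neighbours, such as common enhancers, is a hypothesis consistent with the 172 pairs, but probe sets that read through into the next gene could give the same count, and this was not tested.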
